A study of Homo sapiens with 26 samples.

How the data were processed

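All values were computed from the authors' deposited transcript quantifications, 1 per library, which hold an estimated count, a TPM value and an effective length for each of 257369 transcripts per the file headers. Per the submitters' processing notes, reads were trimmed with cutadapt 4.1, quantified with Salmon (version not given in the sources used here) against GRCh38, and compared with DESeq2 1.44.0. Per the labels' protocols, poly(A) RNA from frozen cell pellets was sequenced as paired 150-base reads. Whether the libraries are stranded is not given in the sources used here.

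Transcripts were joined to genes with GENCODE release 29 by their identifiers, which matched 194437 transcripts (75.5%). A further 11552 transcripts lie on alternate loci and were joined to the gene of the same symbol. Between 92.6% and 95.1% of each library's estimated counts reached a gene in these ways, and 4.94% to 7.35% stayed without a gene. The counts that reached a gene include 1.51% to 2.44% from alternate loci. Estimated counts were summed per gene and rounded. For 653 of 14191 coding genes (4.6%) most reads lay on transcripts annotated as non-coding.

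Levels are counts per M (CPM) scaled with TMM factors. The 3 numbered libraries of each batch at P3 and P5 were summed, which left 14 columns (group by batch) in 5 groups. edgeR 4.0.16 (quasi-likelihood F test, robust dispersion) in R 4.3.3 fitted all 5 groups at once, with 9 residual degrees of freedom, after removal of genes with low counts (minimum count 10, minimum total 15). p-values were adjusted with the Benjamini-Hochberg method over the 18060 genes tested of 56271, and a gene was called changed at an adjusted p under 0.05. The biological coefficient of variation was 33.8%. These p-values measure only the spread between these samples, and nothing in the labels says that the batches came from separate cultures. The 7 comparisons, the 26 gene lists, the rule for named genes, the summing of libraries and the alternatives were fixed before the data were examined, except for 8 alternatives that were added later.

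Named genes are 14 key genes (POU5F1, SOX2, NANOG, PRDM1, TFAP2C, SOX17, NANOS3, KIT, KLF17, DPPA3, ZIC2, DNMT3B, TBXT and UTF1), coding genes among the 10 largest rises or falls of a comparison with at least 10 CPM in the higher group and no overlap between groups, and up to 4 changed members of each gene list. Other genes are said to have been chosen after the values were seen. With 3 columns against 3, chance alone keeps the groups apart for 10% of genes, and for more with the 2 hPGCLC columns against 3.

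Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 25 lists with at least 3 tested members, and again with the correlation estimated from the data. camera compares a list with all other genes. fry of limma tests a list against no change and so does not ask the same question. Their names are core, naive, primed and eight-cell-like pluripotency, primed pluripotency lncRNAs, early PGC, late germ cell and meiosis, amnion and trophoblast, primitive streak and mesoderm, endoderm, neuroectoderm, fibroblast and mesenchyme, epithelial, imprinted genes, DNA methylation machinery, FGF-ERK, BMP, WNT and NODAL-activin response, glycolysis, oxidative phosphorylation, sterol and lipid, interferon response, p53 response, unfolded protein and amino acid stress, and proliferation. Of 347 list genes, 332 were measured. A count "adjusted over the list alone" used the same edgeR p-values with the adjustment made inside the list.

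Depth was 16.3 to 20.4 M reads in hIPSC, 19.1 to 19.2 M in hPGCLC, 17.3 to 26.7 M in P0, 20.3 to 29.6 M in P3 and 17.8 to 30.6 M in P5. A gene without reads in a group was set to a floor of 3 counts over the whole group, which is 0.0541 CPM in hIPSC, 0.107 in hPGCLC, 0.0493 in P0, 0.0151 in P3 and 0.0149 in P5, and its fold is then a lower bound ("at least"). A gene with 1 to 3 reads in a group is given a ratio with a 95% counting interval. These bounds and ratios use reads pooled over each whole group, so they can differ from ratios of the printed means. Floors and intervals cover counting error only. No library was a copy of another, since the lowest chi-square per gene between replicates was 4.27.

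The test was tested on simulated data, with counts drawn from each gene's mean level and dispersion and with 4-fold changes put into 100 genes and 2-fold changes into 100 others (200 genes with 4-fold changes for batches). edgeR recovered 65% of them for hPGCLC against hIPSC (17624 genes, 3 false calls), 82% for P3 against P0 (17671 genes, 7 false calls), 79% for P3 against hIPSC (17649 genes, 3 false calls) and 99% for the batches within P3 (15803 genes, 10 false calls). Of 2-fold changes it recovered 4%, 18% and 7% in the first 3 of these. Most 2-fold changes would therefore be missed.

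The labels number the batches, so columns with the same number were treated as a possible pair in an alternative with batch as a block. The mean correlation of same-number columns was 0.0896 for hPGCLC against hIPSC, 0.149 for P0 against hPGCLC, -0.105 for P3 against P0, 0.147 for P5 against P3, 0.36 for P0 against hIPSC, -0.108 for P3 against hIPSC and -0.101 for P5 against hIPSC. The unblocked test was kept. The names of the files have the numbers 1 and 3 exchanged in every group. Which numbering is right is not given in the sources used here, and the pairs are the same under both.

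Alternatives used DESeq2 1.42.0 (Wald and likelihood ratio tests), limma-voom with a duplicate correlation of 0.306 between libraries of a batch, DESeq2 size factors, counts without the low-count filter, length-scaled counts, a removed trend with gene length and GC content, and each column left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.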

Results

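Gene expression was measured by poly(A) RNA sequencing along a route from human induced pluripotent stem cells (hIPSC) to primordial germ cell-like cells (hPGCLC) and on to embryonic germ cell-like cells (hEGCLC). All 26 libraries came from 1 established human iPSC line, BTAG, which carries fluorescent reporters of the germ cell genes PRDM1 and TFAP2C. The hPGCLC were induced from the iPSC, reprogrammed in a defined medium without feeder cells and then moved stepwise to a conventional medium for human pluripotent cells. There were 3 hIPSC, 2 hPGCLC, 3 hEGCLC P0, 9 hEGCLC P3 and 9 hEGCLC P5 libraries, and P0, P3 and P5 were read as passage numbers. At P3 and P5 each of 3 batches holds 3 numbered libraries, which were summed to 1 value per batch for comparisons between groups. Values are normalised counts per M (CPM) as mean ± SD over the n libraries or batches of a group, unless another unit is named. Where an alternative setting moved the fold of a gene over 1.5 times, its lowest and highest value over the alternatives follow in brackets. Column numbers such as hIPSC 1 follow the labels, while the names of the files have 1 and 3 exchanged in every group.

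The libraries held 16.3 to 30.6 M estimated reads (median 20.9 M), and 15955 to 18319 genes had at least 5 reads. In the hPGCLC library of batch 2, 32.8% of reads were mitochondrial, against 0.925% to 5.92% in all others. In that library 47854 transcripts had reads, against 69812 to 92182 elsewhere. Spearman correlations between replicates were 0.933 to 0.975 in hIPSC, 0.943 in hPGCLC, 0.917 to 0.977 in P0, 0.980 to 0.992 in P3 and 0.970 to 0.993 in P5. The first principal component of the 14 columns held 49.4% of the variance and set hPGCLC (186.7 and 254.5) apart from every other column (-62.3 to 40.9). On the second component, with 17.3%, P0 lay at -42.6, -79.0 and -154.1 for batches 1, 2 and 3, and P5 lay at 25.4 to 29.8. The hIPSC columns spread over 80.2, 26.7 and -18.1 for batches 1, 2 and 3. On the third component of these columns, with 9.1%, hIPSC 1 stood apart at -119.3, against -51.2 to 41.7 for all others. The mean log2 CPM of its neuroectoderm list was 0.204, against -2.57 and -2.48 in hIPSC 2 and 3. All comparisons against hIPSC include this column.

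**Figure D1:**
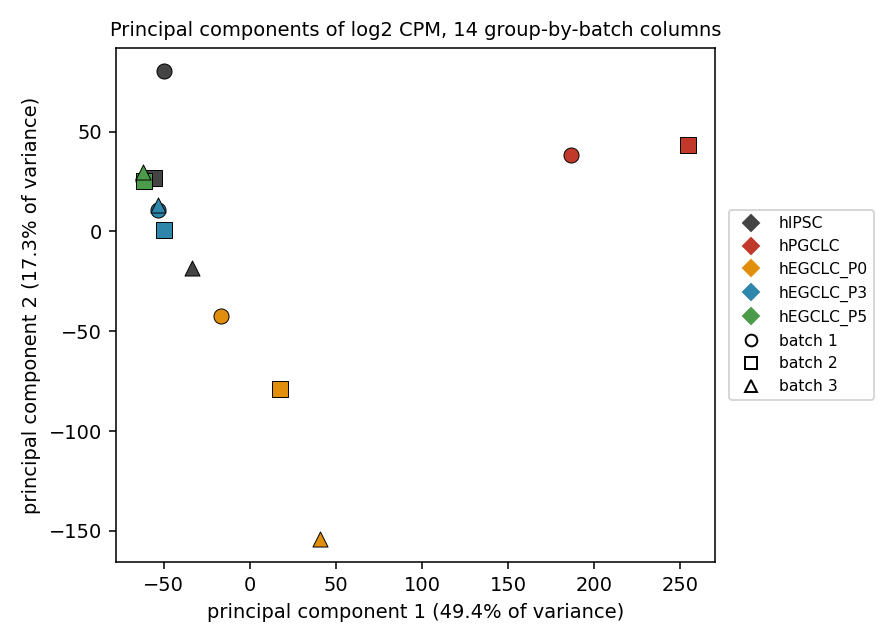
Principal components of the 14 columns (group by batch) from log2 CPM. Each point is 1 column, with symbols for batches 1 to 3 and colours for the groups.

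Conversion of hIPSC to hPGCLC replaced SOX2 with germ cell regulators while POU5F1 and NANOG stayed on. SOX17, which specifies human germ cells, reached 655 ± 11.1 CPM (n = 2) in hPGCLC and had 0 reads in hIPSC, at least 12100-fold higher (edgeR adjusted p = 7.6e-09). NANOS3, an RNA-binding protein that protects germ cells, reached 616 ± 26.3 CPM (n = 2) against 0 reads, at least 11500-fold higher (edgeR adjusted p = 2.1e-05). SOX2, a core pluripotency factor silenced in human germ cells, fell from 323 ± 64.5 CPM (n = 3) to 0 reads, at least 2950-fold lower (edgeR adjusted p = 7.6e-09). In all, 7629 of 18060 genes changed, 3621 higher and 4008 lower in hPGCLC, and 6533 changed at least 2-fold. With only these groups fitted 3749 changed (1879 higher, 1870 lower), and with the length and GC trend removed the balance turned to 4568 higher and 4127 lower.

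PRDM1, a repressor of somatic genes in germ cells, rose by a log2 fold change of 7.26 ± 0.76 (SE), from 0.842 ± 0.322 CPM (n = 3) to 130 ± 5.82 CPM (n = 2). TFAP2C, its partner in germ cell specification, rose by a log2 fold change of 4.15 (edgeR adjusted p = 0.0011), and by 5.98 without hIPSC 1, which held more of it than the other hIPSC libraries. NANOG rose 3.12-fold (edgeR adjusted p = 0.0011) and POU5F1, the shared factor of germ and pluripotent cells, rose 2.06-fold from 3033 ± 784 CPM (n = 3) to 6245 ± 7.85 CPM (n = 2). The POU5F1 call was lost when only these groups were fitted (adjusted p = 4.03e-05 to 0.0649 over its alternatives). ZIC2, a transcription factor of primed pluripotency, fell 598-fold (365 to 724, edgeR adjusted p = 2.2e-07), and DNMT3B, a de novo DNA methyltransferase, fell from 621 ± 90.9 CPM (n = 3) to 7.16 ± 10.1 CPM (n = 2), with 0 reads in hPGCLC 2. TBXT, a mesoderm factor that also acts in germ cell specification, rose 580-fold (282 to 711, edgeR adjusted p = 1.7e-07). DPPA3, a member of the naive pluripotency and early PGC lists, fell 3.16-fold (2.12 to 5.5) to 0.566 ± 0.297 CPM (n = 2). The DPPA3 call was lost without hIPSC 1 or hPGCLC 2 (adjusted p = 0.00944 to 0.211 over its alternatives). KIT, a receptor of migrating germ cells, was not called, at 0.0597 ± 0.0844 CPM (n = 2) in hPGCLC and 4.22 ± 7.09 CPM (n = 3) in hIPSC. UTF1, a chromatin factor of pluripotent and germ cells, was not called, at 150 ± 78.2 CPM (n = 2) against 64.5 ± 58.0 CPM (n = 3).

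The largest rises from 0 reads outside the key genes were CRHBP, which binds corticotropin-releasing hormone, at 528 ± 325 CPM (n = 2), IGF1, a growth factor, at 253 ± 65.7 CPM (n = 2), and WNT2, a WNT ligand, at 85.9 ± 5.14 CPM (n = 2). Among the largest falls, ZIC5, a relative of ZIC2, went from 64.5 ± 40.8 CPM (n = 3) to 0 reads, and FOXD3, a factor of primed cells, went from 45.4 ± 30.1 CPM (n = 3) to 0 reads.

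Of 25 gene lists tested, 10 were called, 6 higher and 4 lower in hPGCLC. The early PGC list was higher (camera adjusted p = 5.3e-08), with 13 rises, 1 fall and 1 gene not called among 15, and 13 rises and 2 falls adjusted over the list alone (adjusted p = 0.054 with an estimated correlation). TCL1A, a kinase co-activator marking germ cells, rose 160-fold, and CXCR4, the receptor that guides their migration, rose 226-fold (153 to 521). The BMP response list was higher (camera adjusted p = 1.9e-06), with all 9 genes up, also adjusted over the list alone (adjusted p = 0.0584 with an estimated correlation), and ID1, a direct BMP target, rose 47.4-fold (37.6 to 93.9) to 1069 ± 174 CPM (n = 2). The amnion and trophoblast list was higher (camera adjusted p = 1.8e-07), with 11 rises, 1 fall and 1 not called of 13, the same adjusted over the list alone (adjusted p = 0.105 with an estimated correlation). CDX2, a trophoblast factor, rose from 2 reads to 33.7 ± 6.64 CPM (n = 2), a ratio of 908 (counting interval 251 to 7510). The primitive streak and mesoderm list was higher (camera adjusted p = 0.0025), with 8 rises, 1 fall and 3 not called of 12, and 8 rises and 2 falls adjusted over the list alone (adjusted p = 0.105 with an estimated correlation). MSX2, a homeobox target of BMP, rose 973-fold to 316 ± 5.11 CPM (n = 2).

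The primed pluripotency list was lower (camera adjusted p = 6.3e-05), with 12 falls, 2 rises and 3 not called of 17, and 13 falls and 2 rises adjusted over the list alone (adjusted p = 0.0584 with an estimated correlation). DUSP6, a feedback phosphatase of ERK signalling, fell 62.0-fold (44.5 to 107). The primed pluripotency lncRNAs were lower (camera adjusted p = 0.042), with 5 falls and 1 rise of 6, the same adjusted over the list alone. That call was lost with batch as a block (adjusted p = 0.0644) and with an estimated correlation (adjusted p = 0.275 with an estimated correlation). ESRG, a lncRNA of primed cells, fell 11.8-fold from 759 ± 208 CPM (n = 3) to 64 ± 4.96 CPM (n = 2). The naive pluripotency list was higher (camera adjusted p = 0.0048), with 8 rises, 3 falls and 1 not called of 12, the same adjusted over the list alone (adjusted p = 0.127 with an estimated correlation), and KLF4, a naive and reprogramming factor with most of its reads on transcripts annotated as non-coding, rose 61.8-fold (48 to 105) to 134 ± 0.148 CPM (n = 2).

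Glycolysis genes were lower in hPGCLC (camera adjusted p = 0.0017), with 12 falls, 1 rise and 2 not called of 15, and 13 falls and 1 rise adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). HK2, which phosphorylates glucose, fell 6.56-fold. Proliferation genes were lower (camera adjusted p = 0.042), with 11 falls and 8 not called of 19, 11 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation), and AURKA, a mitotic kinase, fell 3.12-fold. The fibroblast and mesenchyme list was higher (camera adjusted p = 0.034), with 6 rises, 1 fall and 4 not called of 11, the same adjusted over the list alone (adjusted p = 0.543 with an estimated correlation). POSTN, a matrix protein, rose 281-fold (173 to 367) to 66.8 ± 36.4 CPM (n = 2). The core pluripotency list was not called (camera adjusted p = 0.173), with 4 rises, 5 falls and 5 not called of 14, and 4 rises and 7 falls adjusted over the list alone.

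At P0 the germ cell programme of hPGCLC was down and SOX2 was back. SOX2 rose from 0 reads to 528 ± 87.3 CPM (n = 3), at least 4780-fold higher (edgeR adjusted p = 5.0e-09). SOX17 fell 391-fold to 1.66 ± 0.395 CPM (n = 3), NANOS3 fell 1090-fold (784 to 1830) to 0.512 ± 0.449 CPM (n = 3), and PRDM1 fell 130-fold (85.7 to 350) to 0.992 ± 0.912 CPM (n = 3). TBXT fell 45.7-fold to 1.83 ± 0.869 CPM (n = 3). Between P0 and hPGCLC 6100 genes changed, 3341 higher and 2759 lower in P0, and 5275 changed at least 2-fold. With only these groups fitted 2814 changed (1558 higher, 1256 lower), and with the length and GC trend removed the balance turned to 3534 higher and 3823 lower. The NANOS3 call was lost with DESeq2 (adjusted p = 1.91e-118 to 0.0874 over its alternatives).

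TFAP2C fell 24.0-fold (edgeR adjusted p = 0.00074), NANOG fell 6.15-fold (edgeR adjusted p = 3.9e-05) and POU5F1 fell 2.58-fold to 2424 ± 658 CPM (n = 3). The POU5F1 call was lost when only these groups were fitted (adjusted p = 1.16e-06 to 0.0847 over its alternatives). ZIC2 rose 144-fold to 62.1 ± 9.73 CPM (n = 3). DNMT3B rose to 1194 ± 1320 CPM (n = 3) from 7.16 ± 10.1 CPM (n = 2), a call lost when only these groups were fitted (adjusted p = 2.42e-63 to 0.202 over its alternatives). DPPA3 rose 12.9-fold (9.51 to 22.3) to 7.55 ± 1.58 CPM (n = 3). UTF1 and KIT were not called, with UTF1 at 72.8 ± 45.9 CPM (n = 3) and KIT at 3.83 ± 4.89 CPM (n = 3) in P0. FOXD3 came back from 0 reads to 27.0 ± 12 CPM (n = 3), at least 268-fold higher, and ZIC5 to 26 ± 7.62 CPM (n = 3), at least 246-fold higher. OLFM4, a secreted glycoprotein, went from 26.9 ± 0.707 CPM (n = 2) to 0 reads, at least 545-fold lower.

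Of 25 gene lists 5 were called between P0 and hPGCLC, 3 higher and 2 lower in P0, and with an estimated correlation 0 were called by camera, while fry, which tests each list against no change and not against other genes, called 14. The early PGC list was lower (camera adjusted p = 4.9e-07), with 12 falls, 1 rise and 2 not called of 15, and 12 falls and 2 rises adjusted over the list alone (adjusted p = 0.0803 with an estimated correlation). TCL1A fell 139-fold and CXCR4 fell 229-fold (155 to 456). The primed pluripotency lncRNAs were higher (camera adjusted p = 0.0003), with 6 rises of 6, also adjusted over the list alone (adjusted p = 0.125 with an estimated correlation), and ESRG rose 17.7-fold. The BMP response list was lower (camera adjusted p = 0.00094), with 8 falls and 1 not called of 9, 8 adjusted over the list alone (adjusted p = 0.145 with an estimated correlation), and ID1 fell 3.71-fold. The primed pluripotency list was higher (camera adjusted p = 0.0028), with 11 rises, 4 falls and 2 not called of 17, and 12 rises and 5 falls adjusted over the list alone (adjusted p = 0.145 with an estimated correlation). Glycolysis genes were higher (camera adjusted p = 0.019), with 11 rises, 1 fall and 3 not called of 15, the same adjusted over the list alone (adjusted p = 0.364 with an estimated correlation), and HK2 rose 3.46-fold.

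The P0 libraries differed from hIPSC, with genes of amnion, mesoderm and mesenchyme far above their hIPSC level. In bulk libraries a mixture of cell types and a shift of all cells cannot be told apart. HAND1, a factor of extraembryonic mesoderm and amnion, was at 47.5 ± 25.4 CPM (n = 3) in P0 and had 1 read in hIPSC, a ratio of 2880 (counting interval 517 to 114000). TFAP2A, an amnion and surface ectoderm factor, was at 23.8 ± 6.34 CPM (n = 3) against 1 read, a ratio of 1370 (counting interval 245 to 54100). TBX3, a T-box factor of amnion and naive cells, was at 21.8 ± 13.7 CPM (n = 3) against 0 reads, at least 446-fold higher, and WNT6, an amnion ligand, at 21.3 ± 10.8 CPM (n = 3), at least 403-fold higher. Between P0 and hIPSC 2037 genes changed, 1155 higher and 882 lower in P0, and 1746 at least 2-fold. Without hIPSC 1 the count was 1257, without P0 1 it was 3111 and without P0 2 it was 1076. With only these groups fitted it was 197, and the share higher in P0 moved from 56.7% to 83.2%.

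GATA3, a trophoblast and amnion factor, rose 305-fold (254 to 462) from 0.124 to 39.4 ± 14.8 CPM (n = 3), and COL3A1, a fibrillar collagen, rose 680-fold (337 to 955) to 137 ± 126 CPM (n = 3). SOX17 was at 1.66 ± 0.395 CPM (n = 3) against 0 reads, at least 31.6-fold higher, and TBXT was 12.7-fold (6.37 to 16) higher than in hIPSC (edgeR adjusted p = 0.0017). Whether these levels are left from the germ cell programme was not tested. DPPA3 was 4.08-fold higher (edgeR adjusted p = 0.014) and ZIC2 was 4.17-fold (2.54 to 5.04) lower (edgeR adjusted p = 0.0029), and these calls were lost when only these groups were fitted (highest adjusted p = 0.141 and 0.0862). NANOS3 at 0.512 ± 0.449 CPM (n = 3) against 0 reads was at least 10.9-fold higher, a call lost without hIPSC 1, hIPSC 2, hIPSC 3, P0 1 or P0 2 (adjusted p = 8.73e-10 to 0.399 over its alternatives). POU5F1, PRDM1, TFAP2C, KIT, DNMT3B and UTF1 were not called between P0 and hIPSC, with TFAP2C at 19 ± 6.12 CPM (n = 3) against 25.7 ± 32.2 CPM (n = 3) and DNMT3B at 1194 ± 1320 CPM (n = 3) against 621 ± 90.9 CPM (n = 3). SOX2 was 1.64-fold higher and NANOG 1.97-fold lower (edgeR adjusted p = 0.032 and 0.044). The SOX2 call was lost without hIPSC 2, hIPSC 3 or P0 3 (adjusted p = 0.00276 to 0.261 over its alternatives). The NANOG call was lost without hIPSC 1, P0 1, P0 2 or P0 3 (adjusted p = 0.00245 to 0.267 over its alternatives).

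Among the 25 gene lists, 13 were called between P0 and hIPSC, 10 higher and 3 lower in P0. All 13 genes of the amnion and trophoblast list rose, also adjusted over the list alone (camera adjusted p = 1.3e-21). The primitive streak and mesoderm list was higher (camera adjusted p = 3.0e-08), with 9 rises and 3 not called of 12, 10 adjusted over the list alone, and MSX2 rose 86.3-fold (54.6 to 114). The fibroblast and mesenchyme list was higher (camera adjusted p = 6.4e-08), with 7 rises and 4 not called of 11, 10 adjusted over the list alone (adjusted p = 0.081 with an estimated correlation), and LUM, a matrix proteoglycan, reached 28 ± 23.9 CPM (n = 3) against 2 reads, a ratio of 879 (counting interval 243 to 7270). The endoderm list was higher (camera adjusted p = 3.2e-05), with 5 rises and 6 not called of 11, 8 adjusted over the list alone, and GATA6, an endoderm and amnion factor, was at least 108-fold higher. The naive pluripotency list was higher (camera adjusted p = 6.8e-07), with 7 rises and 5 not called of 12, 9 adjusted over the list alone, and FGF4, a growth factor of epiblast cells, rose 12-fold to 20.8 ± 5.21 CPM (n = 3). The late germ cell and meiosis list was higher (camera adjusted p = 6.9e-05), with 4 rises and 10 not called of 14, 5 adjusted over the list alone. MAEL, a piRNA pathway protein, rose 12.8-fold and TDRD12, a tudor protein of the same pathway, rose 5.59-fold.

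The early PGC list was higher in P0 than in hIPSC (camera adjusted p = 0.0016), with 5 rises and 10 not called of 15, 6 adjusted over the list alone (adjusted p = 0.108 with an estimated correlation). The BMP response list was higher (camera adjusted p = 7.3e-06), with 5 rises and 4 not called of 9, 5 adjusted over the list alone, and ID1 rose 12.8-fold (10.1 to 25.3). The WNT response list was higher (camera adjusted p = 0.0086), with 3 rises and 7 not called of 10, 5 adjusted over the list alone (adjusted p = 0.239 with an estimated correlation), and LEF1, a nuclear effector of WNT, rose 24.6-fold (14.5 to 33.7). The primed pluripotency lncRNAs were higher (camera adjusted p = 0.0015), with 3 rises and 3 not called of 6, 4 adjusted over the list alone (adjusted p = 0.081 with an estimated correlation), and LINC01108 rose 28.3-fold (20.6 to 46.5) to 75.6 ± 36.3 CPM (n = 3). The FGF-ERK response list was lower (camera adjusted p = 1.9e-06), with 7 falls and 8 not called of 15, 10 adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). DUSP6 fell 23.8-fold (17 to 41.4) from 448 ± 262 CPM (n = 3) to 18.7 ± 14.1 CPM (n = 3). The p53 response list was lower (camera adjusted p = 0.0044), with 6 falls and 7 not called of 13, 6 adjusted over the list alone (adjusted p = 0.137 with an estimated correlation). The primed pluripotency list was lower (camera adjusted p = 0.015), with 5 falls and 12 not called of 17, 6 adjusted over the list alone (adjusted p = 0.137 with an estimated correlation), and SFRP2, a secreted WNT antagonist, fell 3.51-fold.

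Between P0 and P3 all 13 amnion and trophoblast genes fell, together with most tested genes of mesoderm and mesenchyme. HAND1 fell 1440-fold (1040 to 4240) to 0.0281 CPM, TFAP2A fell 370-fold (308 to 611) to 0.0621 CPM and NR2F2, a nuclear receptor of mesenchyme, fell 382-fold (266 to 732) to 0.0314 CPM. WNT6 went from 21.3 ± 10.8 CPM (n = 3) to 0 reads, at least 1440-fold lower (edgeR adjusted p = 0.00017). DUSP6, a feedback phosphatase of ERK signalling, rose 13.8-fold (10.5 to 23.3) to 259 ± 9.12 CPM (n = 3; edgeR adjusted p = 0.0013). Between P3 and P0 1227 genes changed, 264 higher and 963 lower in P3, and 1135 at least 2-fold. Without P0 1 the count was 3210, without P3 1 it was 511, without P3 2 it was 528 and without P3 3 it was 412. The share higher in P3 was 21.5%, and it was 37.9% without P0 1, 41.9% with the libraries as separate samples and 47.2% with limma-voom.

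The key genes SOX17, TBXT, TFAP2C, UTF1, NANOS3 and DPPA3 were lower in P3 than in P0. Of these DPPA3 had risen from hPGCLC to P0, and UTF1 was not called there. SOX17 fell from 1.66 ± 0.395 CPM (n = 3) to 1 read over the group, a ratio of 339 (counting interval 59.5 to 13500), and TBXT fell 20.1-fold (9.98 to 28.5) to 0.0876 ± 0.0634 CPM (n = 3). TFAP2C fell 6.78-fold to 2.79 ± 0.982 CPM (n = 3), a call lost without P0 2, P3 1, P3 2 or P3 3 (highest adjusted p = 0.161). UTF1 fell 13.1-fold (5.68 to 20.4) to 5.56 ± 1.72 CPM (n = 3), a call lost without P3 2 or P3 3 (highest adjusted p = 0.0718). NANOS3 went to 0 reads, at least 39.1-fold lower, a call lost without P0 2 or P3 3 (adjusted p = 1.54e-20 to 0.278 over its alternatives). DPPA3 fell 3.42-fold to 2.2 ± 0.453 CPM (n = 3), a call lost without P0 2, P0 3, P3 1, P3 2 or P3 3 (highest adjusted p = 0.121).

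The core factors were not called, with POU5F1 at 2100 ± 30.9 CPM (n = 3), SOX2 at 342 ± 14.6 CPM (n = 3) and NANOG at 119 ± 11.6 CPM (n = 3) in P3. DNMT3B at 1463 ± 236 CPM (n = 3), ZIC2 at 116 ± 7.24 CPM (n = 3), KIT at 3.85 ± 1.18 CPM (n = 3) and PRDM1 at 0.343 ± 0.0737 CPM (n = 3) in P3 were not called. Among the largest rises, SLC1A1, a glutamate transporter, rose 8.16-fold, P2RY1, a receptor for ADP, rose 6.39-fold, and TSHZ3, a zinc-finger factor, rose 6.15-fold to 25.9 ± 6.56 CPM (n = 3).

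Of 25 gene lists 13 were called between P3 and P0, 2 higher and 11 lower in P3. All 13 amnion and trophoblast genes fell, also adjusted over the list alone (camera adjusted p = 1.8e-26). The primitive streak and mesoderm list was lower (camera adjusted p = 1.7e-13), with 10 falls and 2 not called of 12, 10 adjusted over the list alone, and MSX1, a BMP target, fell 134-fold (89.6 to 167). The naive pluripotency list was lower (camera adjusted p = 1.9e-09), with 8 falls and 4 not called of 12, 9 adjusted over the list alone, and FGF4 fell 17.3-fold to 1.2 ± 0.0683 CPM (n = 3). The BMP response list was lower (camera adjusted p = 2.4e-09), with 6 falls and 3 not called of 9, 8 adjusted over the list alone, and ID4, a direct target, fell 12.1-fold. The fibroblast and mesenchyme list was lower (camera adjusted p = 1.5e-08), with 7 falls and 4 not called of 11, 9 adjusted over the list alone (adjusted p = 0.0735 with an estimated correlation), and COL3A1 fell 220-fold (111 to 883). The WNT response list was lower (camera adjusted p = 1.7e-05), with 5 falls and 5 not called of 10, 7 adjusted over the list alone (adjusted p = 0.0735 with an estimated correlation), and LEF1 fell 34.1-fold (20.5 to 46.2). The endoderm list was lower (camera adjusted p = 0.0022), with 4 falls and 7 not called of 11, and 5 falls and 1 rise adjusted over the list alone, and GATA6 fell 86.3-fold (68.6 to 171).

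The early PGC list was lower in P3 than in P0 (camera adjusted p = 0.0011), with 5 falls and 10 not called of 15, 6 adjusted over the list alone (adjusted p = 0.0849 with an estimated correlation). The imprinted genes were lower (camera adjusted p = 0.005), with 5 falls and 15 not called of 20, 7 adjusted over the list alone (adjusted p = 0.127 with an estimated correlation), and IGF2, a paternally expressed growth factor, fell 146-fold from 267 ± 157 CPM (n = 3) to 1.82 ± 0.369 CPM (n = 3). The late germ cell and meiosis list was lower (camera adjusted p = 0.0093), with 3 falls and 11 not called of 14, 5 adjusted over the list alone (adjusted p = 0.0571 with an estimated correlation). The p53 response list was lower (camera adjusted p = 0.018), with 4 falls and 9 not called of 13, 5 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). The primed pluripotency list was higher (camera adjusted p = 0.0086), with 3 rises and 14 not called of 17, and 3 rises and 1 fall adjusted over the list alone (adjusted p = 0.0968 with an estimated correlation), and SFRP2 rose 3.62-fold to 650 ± 20.1 CPM (n = 3). The FGF-ERK response list was higher (camera adjusted p = 0.017), with 4 rises and 11 not called of 15, 4 adjusted over the list alone (adjusted p = 0.463 with an estimated correlation), and SPRY4, a feedback inhibitor of the pathway, rose 4.19-fold. Oxidative phosphorylation genes were not called (camera adjusted p = 0.068) but were called with batch as a block (adjusted p = 0.0472).

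Between P3 and P5 no single gene was called in the 5-group fit, while the p53 response genes were higher at P5 as a list. edgeR called 0 of 18060 genes, with 861 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 65. POU5F1 was at 1892 ± 61.3 CPM (n = 3) in P5 and 2100 ± 30.9 CPM (n = 3) in P3, SOX2 at 260 ± 3.00 and 342 ± 14.6 CPM (n = 3), and NANOG at 113 ± 10.8 and 119 ± 11.6 CPM (n = 3). DNMT3B was at 1073 ± 64.9 CPM (n = 3) in P5, TFAP2C at 4.29 ± 0.439 CPM (n = 3), UTF1 at 5.77 ± 0.83 CPM (n = 3) and KIT at 4.6 ± 0.835 CPM (n = 3). ZIC2 was at 129 ± 11.3 CPM (n = 3), DPPA3 at 1.19 ± 0.236 CPM (n = 3) and PRDM1 at 0.941 ± 0.0204 CPM (n = 3) in P5, and SOX17, NANOS3 and TBXT stayed at 0 reads or near it.

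Of 25 gene lists 4 were called between P5 and P3, 1 higher and 3 lower in P5. Of the 10 splits of these 6 columns, 3 gave as many called lists, the real split included. The number of called lists therefore does not set the real groups apart. The p53 response list was higher (camera adjusted p = 7.3e-14), with 0 of 13 genes called and 7 rises adjusted over the list alone, and it kept its call with an estimated correlation. In the fit of single libraries given below, every member but BAX, FAS and PHLDA3 was called higher. That fit counts numbered libraries as separate samples. The 3 P5 libraries with the highest values on the third component of the single libraries (52.9, 54.8 and 29.9) also held the highest p53 scores (6.27, 6.1 and 5.65), and without them the list was still higher (camera adjusted p = 0.001). In it CDKN1A, a cell cycle inhibitor, was at 66.9 ± 78.5 CPM (n = 9 libraries) in P5 and 13.2 ± 7.17 CPM (n = 9) in P3, and GDF15, a stress cytokine, at 21.9 ± 28.2 and 2.94 ± 1.77 CPM (n = 9). The NODAL-activin response list was lower (camera adjusted p = 0.00028), with 0 of 8 called and 1 adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). In the fit of single libraries NODAL, LEFTY1, LEFTY2, SMAD7, SKIL, GDF3 and TDGF1 were called lower. Of these only SKIL, GDF3 and TDGF1 were also called with only the P3 and P5 batches fitted. The core pluripotency list was lower (camera adjusted p = 0.0081), with 0 of 14 called and 0 adjusted over the list alone (adjusted p = 0.295 with an estimated correlation). In the fit of single libraries POU5F1, SOX2, PRDM14, TDGF1, L1TD1, ZSCAN10 and ZFP42 were called lower, and the other members were not called. The primed pluripotency lncRNAs were lower (camera adjusted p = 0.0081), with 0 of 6 called and 2 adjusted over the list alone (adjusted p = 0.294 with an estimated correlation).

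The 5-group fit takes its spread from all stages. With the 18 P3 and P5 libraries on their own and the library number as a block, 5779 genes changed, 2919 higher and 2860 lower in P5, with a median absolute log2 fold change of 0.41. This fit counts the 9 numbered libraries of a group as separate samples and pairs them by number. The labels say neither that they are separate cultures nor that a number is kept from P3 to P5. If they are repeats of the same culture, only 3 batches count and the p-values of this fit are too low. Fitting only the P3 and P5 batches gave 6346 genes, and 5259 genes were in both sets. Of the 5779 genes 249 rose and 130 fell at least 2-fold. Among the key genes SOX2 fell 1.3-fold (edgeR with the library block, adjusted p = 0.00099) and DPPA3 1.92-fold (adjusted p = 0.0037). DNMT3B fell 1.44-fold and POU5F1 1.11-fold (adjusted p = 0.0404 and 0.0392). PRDM1 rose 2.59-fold and TFAP2C 1.5-fold (adjusted p = 0.0051 and 0.0497), while NANOG, ZIC2, KIT and UTF1 were not called. The following genes were chosen after the values were seen, and their p-values come from edgeR with the library block. SLIT2, a guidance ligand, rose 2.36-fold to 51.8 ± 14.4 CPM (n = 9; adjusted p = 0.0004). CTCFL, a germ line relative of CTCF, rose 3.12-fold to 25.4 ± 9.53 CPM (n = 9; adjusted p = 0.001). PRDM14, a pluripotency and germ line repressor, fell 2.04-fold to 23.8 ± 9.35 CPM (n = 9; adjusted p = 0.0058). ID1 fell 2.62-fold (adjusted p = 0.00085) and MT2A, a metal-binding protein, fell 2.62-fold to 9.63 ± 2.91 CPM (n = 9; adjusted p = 0.00019).

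**Figure D2:**
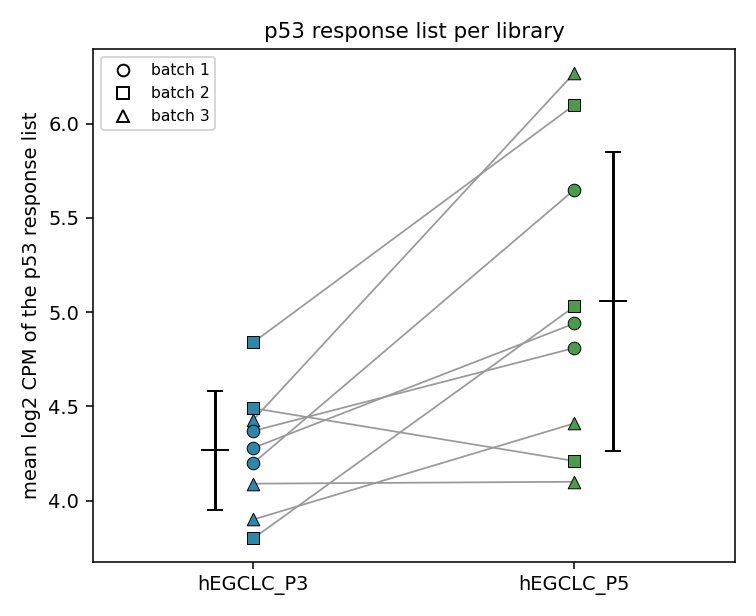
Mean log2 CPM of the p53 response list in the 18 P3 and P5 libraries. Lines join libraries with the same batch and library number, and bars show mean ± SD (n = 9).

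Of 13 p53 response genes 7 were lower in P3 than in hIPSC. CDKN1A fell 5.01-fold, from 63.4 ± 20.6 CPM (n = 3) to 12.7 ± 3.06 CPM (n = 3; edgeR adjusted p = 0.0072). PIWIL2, a piRNA pathway protein of the germ line, rose 5.32-fold to 10.1 ± 1.56 CPM (n = 3; edgeR adjusted p = 0.0071). HPDL, a mitochondrial enzyme, rose 4.22-fold to 36.7 ± 3.74 CPM (n = 3; edgeR adjusted p = 0.0085). ATP8B3, a lipid-flipping ATPase, fell 9.03-fold (edgeR adjusted p = 0.0071).

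Between P3 and hIPSC 321 genes changed, 128 higher and 193 lower in P3, and 295 at least 2-fold. With batch as a block the count was 142, and with only these groups fitted it was 0, so every call named here is lost in that setting. Other settings gave more, with 3751 for the libraries as separate samples, 2469 without hPGCLC 2 and P0 3, 1692 with DESeq2, 1357 with limma-voom, 1289 without the low-count filter and 1135 with the length and GC trend removed, while length-scaled counts gave 105. Without hIPSC 1 the count was 130, without hIPSC 2 it was 671, and without P3 1, P3 2 or P3 3 it was 38, 34 and 32. The share higher in P3 was 39.9%, and it was 55.3%, 67.6% and 68.8% without P3 1, P3 2 and P3 3. TFAP2C had a log2 fold change of -3.19 at 2.79 ± 0.982 CPM (n = 3), and of -1.36 without hIPSC 1, and UTF1 fell 11.6-fold (6.19 to 16.6) to 5.56 ± 1.72 CPM (n = 3), and these calls were lost with batch as a block (adjusted p = 0.0617 and 0.0814). Each was also lost without hIPSC 1, P3 1, P3 2 or P3 3, and UTF1 without hIPSC 3 (highest adjusted p = 0.231 for TFAP2C and 0.215 for UTF1). POU5F1, SOX2, NANOG, ZIC2, DNMT3B, DPPA3, TBXT, KIT and PRDM1 were not called.

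Between P3 and hIPSC 4 of the 25 gene lists were called, with 1 higher and 3 lower in P3. Of the 10 splits of these 6 columns, 4 gave at least as many called lists, the real split included. The highest other split gave 6, so the number of called lists does not set the real groups apart. The p53 response list was lower (camera adjusted p = 4.6e-09), with 7 falls and 6 not called of 13, 10 adjusted over the list alone, and it kept its call with an estimated correlation. Glycolysis genes were lower (camera adjusted p = 2.3e-05), with 3 falls and 12 not called of 15, 4 adjusted over the list alone (adjusted p = 0.157 with an estimated correlation). The FGF-ERK response list was lower (camera adjusted p = 0.00091), with 3 falls and 12 not called of 15, 6 adjusted over the list alone (adjusted p = 0.585 with an estimated correlation). The primed pluripotency lncRNAs were higher (camera adjusted p = 0.00091), with 2 rises and 4 not called of 6, 3 adjusted over the list alone (adjusted p = 0.157 with an estimated correlation). LINC01108 rose 8.04-fold (6.25 to 13.3) to 21.4 ± 8.16 CPM (n = 3), a call lost without P3 1 (adjusted p = 0.0591). PGK1, a glycolytic kinase, fell 2.31-fold to 815 ± 151 CPM (n = 3), a call lost without P3 2 or P3 3 (highest adjusted p = 0.0917).

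At P5 10 genes were called against hIPSC, all higher in P5, while other settings called from 0 to 427, and 277 of the 427 were lower. All of the 10 genes are named, and apart from PIWIL2 they were chosen after the values were seen. None is particular to P5, since all 10 were also called against hIPSC in P3 and 9 in P0. Their means were above hIPSC at both stages. These comparisons share the hIPSC libraries. MAGEA3 and MAGEA6, near-identical cancer-testis antigens on the X chromosome that share reads, were at 6.54 ± 3.25 and 3.69 ± 2.14 CPM (n = 3) in P5. MAGEA6 had 0 reads in hIPSC and was at least 65.9-fold higher. PIWIL2 rose 5.77-fold to 10.9 ± 0.872 CPM (n = 3; edgeR adjusted p = 0.016). ZNF662, a zinc-finger gene, reached 5.36 ± 2.25 CPM (n = 3), a ratio of 99.1 (counting interval 33.8 to 481), and KRBOX1, which overlaps it on chromosome 3, was at least 28.4-fold higher at 1.53 ± 0.622 CPM (n = 3).

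C9orf64, a queuosine salvage enzyme, rose 12.7-fold (9.84 to 20.7) to 9.44 ± 1.63 CPM (n = 3; edgeR adjusted p = 0.016), and RTP1, a chaperone of odorant receptors, rose 4.44-fold (edgeR adjusted p = 0.028). BHMT2, a methyltransferase of methionine metabolism, reached 1.02 ± 0.188 CPM (n = 3), a ratio of 57.2 (counting interval 10.1 to 2270), ZNF560 was at least 29.9-fold higher, and the lncRNA gene Z83851.2 at least 20.7-fold higher. At an unadjusted p under 0.05 there were 1157 genes, and 8 were called with batch as a block, where BHMT2, RTP1 and Z83851.2 were lost (adjusted p = 0.0509, 0.0661 and 0.103). The count was 17 without hIPSC 1, 67 without hIPSC 2, 0 without hIPSC 3, 0 without P5 1, 6 without P5 2, 6 without P5 3 and 0 with only these groups fitted (highest adjusted p of the 10 genes without a column = 0.161). The share higher in P5 was 100%, and it was 35.1% of 427 genes without the low-count filter, 83.3% of 6 with the length and GC trend removed, 23.9% of 355 with libraries as separate samples, 37.8% of 156 with DESeq2, 64.7% with limma-voom, 64.7% without hIPSC 1 (11 higher, 6 lower), 35.8% without hIPSC 2 (24 higher, 43 lower) and 81% without the 3 P5 libraries that stand apart (17 higher, 4 lower). That all were higher therefore depends on the tool, on the low-count filter, on the summing of libraries and on single hIPSC libraries.

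Of 25 gene lists 8 were called between P5 and hIPSC, 2 higher and 6 lower in P5, and 0 with an estimated correlation, while fry, with its other null of no change, called 2. Glycolysis genes were lower (camera adjusted p = 5.3e-08), with 0 of 15 called and 4 falls adjusted over the list alone (adjusted p = 0.083 with an estimated correlation). The FGF-ERK response list was lower (camera adjusted p = 0.0011), with 0 of 15 called and 1 adjusted over the list alone (adjusted p = 0.387 with an estimated correlation). Oxidative phosphorylation genes were lower (camera adjusted p = 0.0025), with 0 of 16 called and 0 adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). The core pluripotency list (0 of 14 called, 1 adjusted over the list alone) and the epithelial list (0 of 12 called, 0 adjusted over the list alone) were lower (camera adjusted p = 0.017 for each, adjusted p = 0.335 with an estimated correlation). The p53 response list was lower (camera adjusted p = 0.036), with 0 of 13 called and 0 adjusted over the list alone (adjusted p = 0.387 with an estimated correlation). In mean log2 CPM the core, epithelial, FGF-ERK and p53 lists overlapped between the groups. hIPSC 1 was the highest column in each (8.033, 6.509, 6.845 and 5.539). hIPSC 2 and 3 were at 7.334 and 7.702, 6.076 and 6.103, 5.955 and 5.614, and 5.179 and 5.325. P5 lay at 7.315 to 7.366, 5.972 to 6.087, 5.601 to 5.791 and 5.146 to 5.378. These calls were not tested without hIPSC 1. The primed pluripotency lncRNAs were higher (camera adjusted p = 0.0048), with 0 of 6 called and 2 adjusted over the list alone (adjusted p = 0.255 with an estimated correlation). The late germ cell and meiosis list was higher (camera adjusted p = 0.0048), with 1 rise, PIWIL2, and 13 not called of 14, 2 adjusted over the list alone (adjusted p = 0.083 with an estimated correlation). Without the 3 P5 libraries that stand apart the calls of the core pluripotency (adjusted p = 0.084) and late germ cell and meiosis lists (adjusted p = 0.0587) were lost.

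Lists never called in any comparison were DNA methylation machinery (lowest camera adjusted p = 0.123, 9 genes), interferon response (0.133, 9 genes), neuroectoderm (0.113, 7 genes), unfolded protein and amino acid stress (0.282, 10 genes) and sterol and lipid synthesis (0.0502, 14 genes). The sterol and lipid list was called for hPGCLC against hIPSC with batch as a block (adjusted p = 0.0235). None of the 11 eight-cell-like genes reached the level for a test, with the highest column at 0.28 CPM, for KDM4E. KLF17, a factor of naive cells and the 8-cell stage, had at most 2 reads in any column.

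Of the 7629 genes that differed between hPGCLC and hIPSC, 1152 differed from hIPSC in the same direction in P0, 647 higher and 505 lower, against 427.3 for independent sets and 143 in the opposite direction. In P3 147 did so, against 68.5 for independent sets and 34 in the opposite direction. In P5 0 did so, against 2.0 for independent sets, and edgeR therefore called 0 genes in all 3 stages, while DESeq2 called 20. These overlaps share the hIPSC libraries, so part of them may come from shared controls, and how large that part is stays open. Data simulated with shared hIPSC libraries and no true change gave means of 0, 0.05 and 0 genes in P0, P3 and P5, but with a mean of only 0.1 hPGCLC calls they do not bear on overlaps between large sets of calls. MSX2 and GATA4, a factor of endoderm and heart, were among the genes higher in hPGCLC and in P0 than in hIPSC.

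Within P3 15 genes differed among the 3 batches, among them the NODAL antagonists LEFTY1 and LEFTY2 and the heat shock genes HSPA1A and HSPA1B, which were chosen after the values were seen. Within P5 edgeR called 0 genes among batches, and DESeq2 called 5. Of 100 splits of the P3 libraries, with the real split among them, 5 gave at least 15 genes, so chance was not excluded for these 15 genes.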

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

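A Dixon outlier test looked at the 9 libraries of P3 and of P5 for each key gene, list score and depth value. It marked 7 of 84 values by the ratio of the gap to the range, where about 1 in 20, or 4.2, would be marked by chance. The differences were not tested further.

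At P3, SOX17 was at 0.0492 CPM in library 3 of batch 2 and at 0 in the median of the others (Dixon ratio 1). This mark rests on 1 read, the only SOX17 read in P3. KIT was at 0 CPM in the same library against 3.98 CPM (Dixon ratio 0.521). DPPA3 was at 1.11 CPM in library 1 of batch 2 against 2.54 CPM (Dixon ratio 0.54). Library 2 of batch 1 held 29.6 M reads against 21.1 M (Dixon ratio 0.755).

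At P5, NANOG was at 145 CPM in library 2 of batch 1 against 116 CPM (Dixon ratio 0.537). The primitive streak and mesoderm score was -0.976 in that library against -1.27 (Dixon ratio 0.532). SOX17 was at 0.113 CPM in library 3 of batch 3 against 0 (Dixon ratio 0.562), with only 4 reads over all P5 libraries.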

How the results depend on the processing

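The numbers below limit the results most where groups are close. Of the counts of genes or lists under alternative settings 124 stayed within 1.5 times and 70 moved. The balance of higher and lower calls turned for hPGCLC against hIPSC with the length and GC trend removed (4568 higher, 4127 lower) and with only these groups fitted (1879, 1870), and for P0 against hPGCLC with the trend removed (3534, 3823). It also turned for P3 against hIPSC without P3 1 (21, 17), P3 2 (23, 11) or P3 3 (22, 10), and for P5 against hIPSC without the low-count filter (150, 277), with the libraries as separate samples (85, 270), with DESeq2 (59, 97) and without hIPSC 2 (24, 43). For 236 named gene results 3604 of 3902 alternative values kept the call, 298 lost it and 0 changed sign, while the fold of 136 moved over 1.5 times in some alternative and that of 91 with a column left out. Among the calls described here, batch as a block changed no other than those given in the report, SIX6 (0.0501) and SOX14 (0.0758) in P0 against hIPSC, and GDF15 (0.0532), IER3 (0.0549) and EGR1 (0.0743) in P3 against hIPSC.

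With only the compared groups fitted, the gene counts were 3749 for hPGCLC against hIPSC (7629), 2814 for P0 against hPGCLC (6100), 6346 for P5 against P3 (0), 197 for P0 against hIPSC (2037), 0 for P3 against hIPSC (321) and 0 for P5 against hIPSC (10).

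Other counts of P3 against P0 (1227) were 2856 without the low-count filter, 5938 with the libraries as separate samples, 2563 with DESeq2, 4351 with limma-voom and 412 to 3210 with a column left out. For P0 against hIPSC they were 3496, 4633, 3626 and 3530 in the same order, and 1076 to 3111 with a column left out. For P3 against hIPSC they were 1289, 3751, 1692 and 1357, and 142 with the block, 105 with length-scaled counts, 1135 with the length and GC trend removed, 2469 without hPGCLC 2 and P0 3, and 32 to 671 with a column left out. For P5 against hIPSC they were 427, 355, 156 and 17, and 3 with length-scaled counts, 6 with the trend removed, 21 without the 3 P5 libraries that stand apart (which ended the call of ZNF560, adjusted p = 0.0597), and 0 to 67 with a column left out. For P5 against P3 (0) they were 96, 1918, 65 and 0, and 1 with the trend removed, 3 without hPGCLC 2 and P0 3, 0 without the 3 P5 libraries, 634 in batch 1 alone, 3 in batch 2 alone, 0 in batch 3 alone and 5779 with the library block. For hPGCLC against hIPSC and P0 against hPGCLC leaving out a column gave 5925 to 8097 and 4619 to 6914.

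Batches within P3 (15 genes) gave 88 without the filter, 8 with length-scaled counts and 176 with the DESeq2 likelihood ratio test, and batches within P5 (0) gave 2 without the filter and 5 with that test. Genes retained in all 3 stages (0) were 84 without the filter and 20 with DESeq2.

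With an estimated correlation the gene list calls went from 10, 5, 13, 4, 13, 4 and 8 to 0, 0, 5, 1, 6, 1 and 0, in the order hPGCLC against hIPSC, P0 against hPGCLC, P3 against P0, P5 against P3, P0 against hIPSC, P3 against hIPSC and P5 against hIPSC. The P0 against hPGCLC lists were 9 without the filter.

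List calls lost elsewhere were, with the length and GC trend removed, proliferation in hPGCLC against hIPSC (0.0692; 0.0706 with length-scaled counts), glycolysis in P0 against hPGCLC (0.0675), early PGC (0.0656), FGF-ERK (0.14) and p53 (0.0536) in P3 against P0, primed lncRNAs in P5 against P3 (0.151), and epithelial (0.207), oxidative phosphorylation (0.0536) and p53 (0.102) in P5 against hIPSC. Without hPGCLC 2 and P0 3 they were glycolysis in P0 against hPGCLC (0.0752), primed lncRNAs in P5 against P3 (0.101) and primed in P0 against hIPSC (0.24). With length-scaled counts they were core (0.055) and p53 (0.0591) in P5 against hIPSC. The calls of named genes that stayed without each column in turn were 62 of 63 in hPGCLC against hIPSC, 41 of 42 in P0 against hPGCLC, 34 of 45 in P3 against P0, 45 of 51 in P0 against hIPSC, 5 of 25 in P3 against hIPSC and 0 of 10 in P5 against hIPSC.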

Other observations

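Several changes of hPGCLC lie outside the groups described so far. EGR1, an immediate early gene, rose 18-fold over hIPSC to 417 ± 68.6 CPM (n = 2; edgeR adjusted p = 5.5e-06) and FOS, its partner in that response, rose 12.8-fold, while CCND1, a cyclin driven by ERK, fell 9.46-fold. TET2, which oxidises methylated cytosine, rose 5.54-fold, and DNMT3L, a cofactor of methylation, rose 109-fold to 20.2 ± 6.03 CPM (n = 2). MX1, an antiviral GTPase, rose 24.5-fold (13.4 to 34.7) to 38.5 ± 22.9 CPM (n = 2). SNRPN, an imprinted splicing gene, fell 5.64-fold.

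In P0, DND1, an RNA-binding protein of germ cells, was at 9.75 ± 1.89 CPM (n = 3) and higher than in hIPSC, a call lost when only these groups were fitted. DLK1, a paternally expressed gene, was higher than in hIPSC by a log2 fold change of 5.49 (4.31 without P0 2) at 41.8 ± 40.8 CPM (n = 3), and it fell to P3. FOXA2, an endoderm factor, was higher in P3, at 5.5 ± 1.69 CPM (n = 3), than in hIPSC, a call lost without P3 1, P3 2 or P3 3 (highest adjusted p = 0.111).

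The first pattern weighed is the amnion and trophoblast genes higher in P0 than in hIPSC, with all of its tests chosen after the result was seen. All 13 genes were still called without the P0 library of batch 3, and 13 with the length and GC trend removed. Carry-over of hPGCLC would need a median of 125% of the hPGCLC level, and 8 of 13 genes stood over 100% (GABRP 3120%), which carried-over cells alone cannot give. The test first written asked the highest share of 20 abundant hPGCLC transcripts to stay at 10% of that need or less, and it was not met (TBX3 62.7%, CFC1 44.8%, NBPF20 18.4%, a gene without a name 49.9%), but it is dropped, because carried-over cells bring all transcripts together and the lowest shares, not the highest, limit them (OLFM4 0%, NANOS3 0.0832%, SOX17 0.253%, median 0.575%). A transient amnion-like state in P0 remains a hypothesis. Carry-over of a few amnion-like cells was not tested, and neither was a mixture of amnion-like and other cells. Staining of single cells for TFAP2A, HAND1 and SOX2 could test these.

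The second pattern is the p53 response list higher in P5 than in P3, with all of its tests chosen after the result was seen. Its mean log2 CPM was 5.06 ± 0.794 (n = 9) in P5 and 4.27 ± 0.319 (n = 9) in P3, and 8 of 9 libraries were higher than their partner of the same batch and number, by 0.792 on average (SD 0.702; exact p = 0.0117 over all sign flips). Regrouping within batches gave an exact permutation p of 0.0132, the list kept an adjusted p of 1.6e-12 or lower without any 1 P5 batch, and the adjusted p was 1.07e-10 with the length and GC trend removed. Depth did not differ detectably between the groups (21.9 ± 4.48 against 22.2 ± 2.84 M reads, n = 9; exact permutation p = 0.9). Within P5 the list score did not follow depth detectably (Pearson r = -0.161, permutation p = 0.693). With 9 libraries a part played by depth is not excluded. If the numbered libraries of a batch are repeats of 1 culture, which the labels leave open, only 3 batches count. For these, sign flips give an exact p of 0.25 and cannot tell chance apart. Without the 3 P5 libraries with the highest scores (6.27, 6.1 and 5.65), which also stand apart on the third component, 5 of 6 pairs were higher by 0.43 on average, so the explanation stays open.

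The third pattern is genes on in some libraries and off in others that match between P3 and P5 libraries of the same batch and number, chosen after the values were seen. Of 66 genes that varied at least 16-fold between libraries, the mean correlation was 0.111 (highest other relabelling 0.192), and a share of 0.0833 of all relabellings within batches were as high, so chance was not excluded. A second count, chosen after the first was seen, found 8 genes with a correlation over 0.8 (COL22A1, CHCHD2, LINC00664, MAGEA3, MAGEA6, MEG3, NNAT and ZFP41, of which MAGEA3 and MAGEA6 share reads) and a share of 0.0139, while another relabelling also reached 8 (median 2). A permutation over all 9 libraries, which also mixes batches, gave p = 0.0405. The statistics differ, the labels do not say whether the library number names a clone kept from P3 to P5, and no explanation is offered.

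The 6 columns of a comparison can be split in only 10 ways, too few for a share under 0.05. For called genes the real split and the highest other gave 1227 and 1 for P3 against P0 (1 of 10 splits as large), 0 and 0 for P5 against P3 (10 of 10), 2037 and 93 for P0 against hIPSC (1 of 10), 321 and 0 for P3 against hIPSC (1 of 10) and 10 and 0 for P5 against hIPSC (1 of 10). With only P3 and P5 fitted they gave 6346 and 0 (1 of 10). For called lists they gave 13 and 9 (1 of 10), 4 and 4 (3 of 10), 13 and 11 (1 of 10), 4 and 6 (4 of 10) and 8 and 6 (1 of 10) in the same order. Among batches within P3 the real 15 genes were reached by 5 of 100 splits (highest 206), and within P5 the real 0 by 100 of 100 (highest 5146). The real split is included in each of these counts. The P5 splits with the most genes put library 1 of batch 3, library 1 of batch 2 and library 2 of batch 1 together, which points to a structure of the samples that batches do not follow, and these libraries also had the highest p53 scores of P5 (6.27, 6.1 and 5.65).

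A test of whether the change from P3 to P5 differed between batches called 0 of 16780 genes in edgeR, with 441 at an unadjusted p under 0.05, and on simulated data it recovered 93% of 4-fold differences with 11 false calls.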
